A study of Mus musculus with 3 samples.

How the data were processed

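Sperm from the cauda epididymis of C57BL/6 mice was profiled by MBD-seq, in which fragments bound by the methyl-CpG-binding protein MBD2 are sequenced, so that read density follows the amount of methylated CpG. Per the labels' protocols, mice received doxorubicin (DXR), a DNA-intercalating topoisomerase II poison, or saline by intraperitoneal injection 2 times a week for 5 weeks, starting at 8 weeks of age. Sperm was collected 4 days after the last dose. Genomic DNA was sonicated to about 300 bp, enriched for methylated DNA, made into libraries and sequenced on a MiSeq instrument, per the labels' protocols and the series design text. There were 3 libraries, with 1 per group: vehicle control, low dose DXR (0.02 mg/kg) and high dose DXR (0.2 mg/kg). How many animals contributed to each library is not given in the sources used here.

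The authors deposited 1 table for the series, a methylation report over the genome in windows of 500 bp. Per the file headers, windows were annotated against Ensembl transcripts (release dated 2013, month 4, day 3), with 500 bp taken as the reach of upstream and downstream. The genome build was mm10, per the submitters' processing notes. The aligner, the read filters and the program that made the report are not given in the sources used here. Per the file headers, the deposited RPM values are read densities per window, scaled by the authors to library size. The deposited RMS and AMS values are methylation scores per window and library, and the headers do not spell these abbreviations out. Checked on the values, RMS divided by AMS was the same in all 3 libraries for a window and was a multiple of 0.2, from 0.4 to 16.4. This quotient is called the factor here and served as a stand-in for CpG content, although the headers do not define it. The authors also deposited a ratio of low dose RMS to control RMS. It differed from that quotient in 0 windows by more than 0.01 percent and had no value in 7 windows where the control was at 0.

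The table held 297037 lines for 143198 windows, since a window was listed once per transcript and effect; each window was counted once. Tested on the values, every window had RMS above 1 in at least 1 library, so the table is a filtered list. Windows that were low in all 3 libraries were not analysed here. The filter admitted 20435 windows on the control library alone, 5937 on the low dose library alone and 2971 on the high dose library alone. In the table, 19 gene symbols had been turned into calendar dates and were not named.

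The number of reads behind a window is unknown. All RPM values of a library (100%, within 0.01 of a step) were whole multiples of 1 step, but no header says that a step is 1 read, and a mean over shorter bins within a window would also give such steps. The step was 0.0214 in the control library, 0.0197 in the low dose library and 0.0216 in the high dose library. If a step stands for the same number of reads in each library, the relative depth was 1.09 for the low dose library and 0.993 for the high dose library, with the control at 1. No counting interval could be computed for single windows.

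The change in a window was log2((treated RMS + c)/(control RMS + c)). The pseudocount c was 0.766, the 10th percentile of RMS values above 0 over the 3 libraries, so that changes of low windows are understated. A window counted as higher or lower at a change of 1 or more in size, which is 2-fold on this scale. Medians over windows carry 95% order-statistic intervals, which cover the spread over windows and not that between animals. With 1 library per group there were no replicates, no test and no p-values, and no difference has a replicate check. Every difference below is one between these libraries.

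Named genes followed a rule. For each treated library against the control, windows annotated to a gene were kept where the larger RMS was at or above 1.68, the median of values above 0. The 10 genes with the largest change upward and the 10 with the largest change downward were taken, by 1 window each; 1 of those at the low dose is not reported here but is included in counts. Predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs, 5S rRNA copies, and olfactory and vomeronasal receptors were counted but not named. Members of 16 gene lists were named as examples, up to 4 per list, together with imprinted genes that had an upstream or first-exon window. Outside this rule, Kit, Ret, Zbtb16, Airn, Mov10l1, Atm, Tnfrsf10b and Dnmt1, list members with a window past the limit, were named after their values were seen. A first-exon window is one that overlaps exon 1 of any annotated transcript, which need not be the main promoter. The lists covered paternally and maternally methylated imprinted loci, germline-specific genes, spermatid and sperm genes, spermatogonial genes, and Sertoli and Leydig cell genes. They also covered leukocyte and epididymal epithelium genes, the DNA damage response, anthracycline transport, oxidative stress defence, apoptosis, and DNA methylation and chromatin machinery. Hox genes, other developmental regulators, housekeeping genes, and olfactory and vomeronasal receptors completed them. List members were matched by symbol, or by an older symbol in the RefSeq gene table of assembly GRCm38.p6 where that symbol belongs to no other gene. A gene's value was the mean change over its windows. The median over a list was set against 10000 random lists of the same size matched on mean RMS, and its percentile among them describes these libraries only.

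Both treated libraries share 1 control library, which gives overlap, and changes of like sign at both doses, without any effect. The 3 values within each window were therefore shuffled 100 times, and the overlap of independent lists was computed as well. The comparisons, the naming rule, the lists and most alternatives were fixed before the data were examined. The alternatives fixed then were a pseudocount multiplied or divided by 3, division of each library by its median, quantile normalization, only windows at or above the median mean, autosomes only, each gene counted once, and limits of 1.5-fold and 4-fold. Gene lists were also computed with the window of largest value per gene. Added after seeing the data were RPM in place of RMS, only windows with RMS above 1 in all 3 libraries, the same restriction for the deciles of mean RPM, and subtraction of the median change of windows of like mean RPM (20 bins) and like factor (8 bins).

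The computation was tested on simulated data made from the control library's 143198 values with log2 noise of SD 0.2. Windows to be changed were drawn from those with RMS at or above the control library's lower quartile, 1.24. In 1 run, 20.5% of 200 windows changed by 2-fold passed the limit, 71.5% of 200 changed by 3-fold and 91.5% of 200 changed by 4-fold, with 0 in the wrong direction. Repeats of the same simulation gave 11.5%, 67.5% and 89%, and 11%, 73% and 87.5%, each of 200 windows. All runs used the control values for both libraries, so they do not describe the comparisons apart. The real changes over windows had an SD of 0.39 at the high dose and 0.36 at the low dose, more than this noise gives. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No reference genome sequence was used here, so base composition was not computed.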

Results

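DNA methylation in mouse sperm was measured by MBD-seq after repeated low or high doses of DXR or saline, with 1 library per group. The series title places the study in the field of DXR-induced testicular toxicity. The data comprised 143198 windows of 500 bp on mm10, of which 82105 were annotated to a gene, with 15181 gene symbols. By annotation, 38217 windows were exonic, 42798 intronic and 61093 intergenic. The median RMS was 1.80 in the control library (interquartile range 1.24 to 2.80), 1.67 in the low dose library (1.09 to 2.75) and 1.57 in the high dose library (0.969 to 2.71). RMS exceeded 1 in 91.0% of windows in the control library, 80.4% in the low dose library and 73.5% in the high dose library. The sum of RMS over windows was 95.8% of control in the low dose library and 93.2% in the high dose library. Read depth per window is unknown.

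The first comparison asked which regions differed in sperm after the high dose. The window with the largest downward change lay in exon 5 of Sdc1 (ENSMUSG00000020592; chromosome 12, 8792501 to 8793000), which encodes the cell-surface proteoglycan syndecan-1. Its RMS was 3.41 in the control library, 1.45 at the low dose and 0.201 at the high dose, a change of -2.11. An exonic window of Adcy9, an adenylyl cyclase gene (chromosome 16, 4307001 to 4307500), had RMS 2.27 in the control library and was listed at 0 at the high dose. A window at exon 1 of Meis2, a homeodomain transcription factor gene (chromosome 2, 116049501 to 116050000), went from 2.68 to 0.145. The largest upward changes were in an intron of the noncoding gene AC102862.2 (chromosome 8, 47388501 to 47389000), with RMS 0.709 in the control library and 3.83 at the high dose, and in exon 5 of Chl1.

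Chl1 (ENSMUSG00000030077; chromosome 6, 103649001 to 103649500) encodes a neural cell adhesion molecule, and its window had RMS 0.556 in the control library, 1.86 at the low dose and 3.21 at the high dose. A single window on chromosome 10 (81273501 to 81274000) covered exon 20 of Tjp3, a tight junction gene, and the downstream flank of Apba3. Its RMS was 5.44 at the low dose and 7.25 at the high dose, changes of 1.17 and 1.54 from the control library. Mcm10, which encodes a DNA replication initiation factor, had an exonic window with RMS 2.76, 5.69 and 7.49 in the same order. Windows of Ppm1h, Opa3, Anp32a, Hnrnpul1 and RP24-67K5.1 completed the upward group, with changes from 1.19 (RP24-67K5.1) to 1.41 (Ppm1h). The other 7 genes of the downward group were Glt25d1, Itgb7, AC126552.1, Btbd11, Pfkm, Col13a1 and Fnbp1. Among these, the exon 9 window of the leukocyte integrin gene Itgb7 went from RMS 2.97 to 0.246, and an intronic window of the glycolytic gene Pfkm from 2.90 to 0.257. All 20 named changes had the same sign at the low dose, which the shared control library favours. Of all windows lower at the high dose, 98.5% were also below control at the low dose. Of all windows higher at the high dose, 98.3% were also above it. With the pseudocount multiplied by 3, 3 of the 10 upward and 7 of the 10 downward windows stayed past the limit. Control RPM was low in some downward windows, at 1.41 for Adcy9, 1.28 for Btbd11 and 1.07 for Col13a1, against a library median of 2.42. Sdc1 (2.74) and AC126552.1 (3.47) lay above that median. No counting interval could be computed, so counting noise in these extremes of all windows was not excluded.

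**Figure D1:**
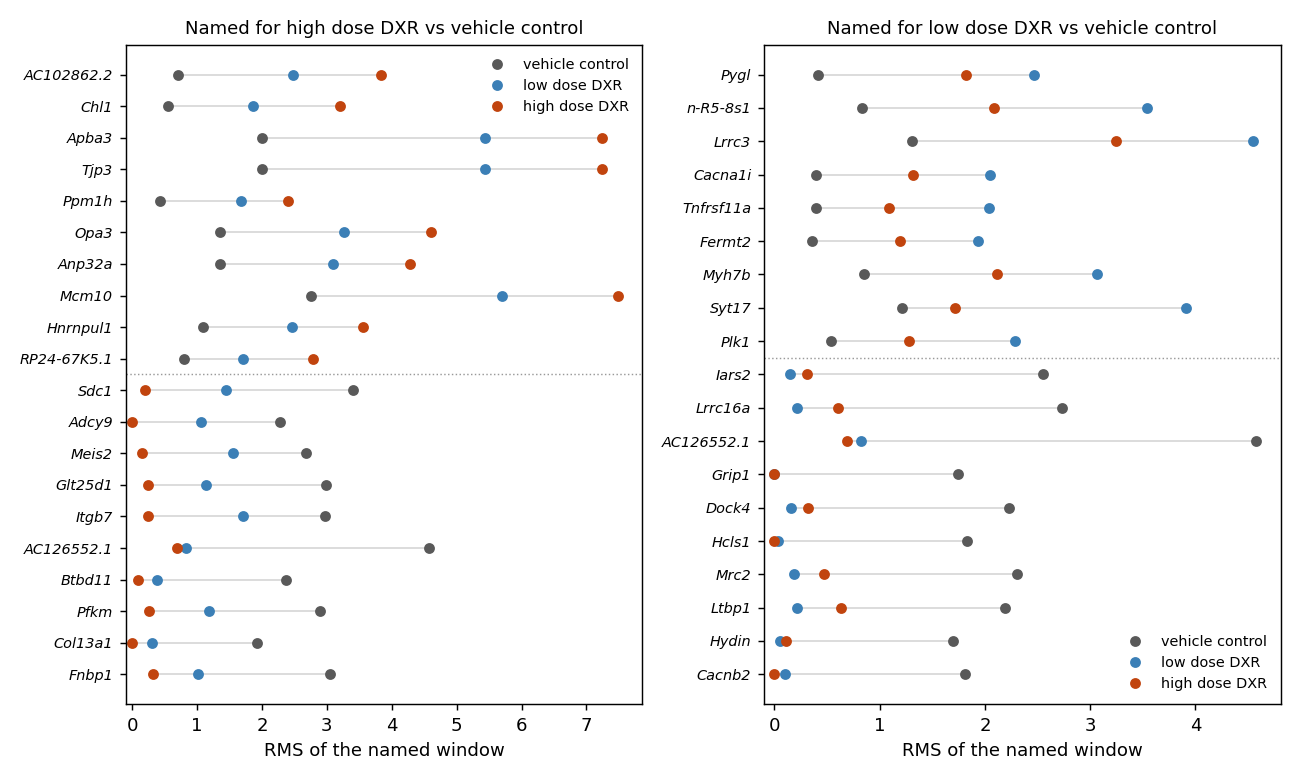
RMS (horizontal axis, methylation score of 1 window per gene) in the control, low dose and high dose libraries for the genes named at the high dose (left) and at the low dose (right), with upward changes above the dotted line and downward changes below it. Each point is 1 library. Sdc1 runs from 3.41 in the control library to 0.201 at the high dose. At the left the low dose point of every gene lies between the other 2, which the choice of the largest high dose changes favours.

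Over all windows, 118 were higher and 3605 lower at the high dose, and the median change was -0.10 (95% interval -0.11 to -0.10). Past the limit and the level required for naming were 53 genes with a higher window and 1002 genes with a lower window. Scaling changed this picture: quantile normalization gave 694 higher and 993 lower windows, division by library medians gave 335 and 2213, and these moved the median by 0.11 and 0.14, to above 0. Subtraction of the trend in RPM and factor gave 989 higher and 424 lower windows, and dividing or multiplying the pseudocount by 3 gave 12168 or 15 lower ones. The windows of all 20 named genes, Sdc1 and Chl1 among them, kept their direction and stayed past the limit under the 3 scalings. Their choice for the largest changes favours this.

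Windows of low RPM made up most of the lower group. In the lowest decile of windows by mean RPM, the median change at the high dose was -0.51 and 12.8% of windows were lower. In the highest decile it was 0.13, and 0 windows were lower. The low dose library followed the same order, with medians of -0.39 and 0.08 in these deciles. The filter on RMS shapes the lowest decile: among windows with RMS above 1 in all 3 libraries, the high dose medians of the lowest and highest deciles were -0.09 and 0.14. Windows with a factor of 8.2 or more, the most CpG-rich by this stand-in, had a median change of 0.26 at the high dose. Introns had a median change of -0.17 at the high dose with 3.36% of windows lower, exons -0.11 with 2.30%, and intergenic windows -0.06 with 2.06%. First exons had a median of -0.09 over 5808 windows, and the 405 upstream windows a median of -0.08. After the trend in RPM and factor was subtracted, the medians were -0.02 for introns, 0.003 for exons and 0.01 for intergenic windows. On the X chromosome the median change was 0.04 (3518 windows) and on the Y chromosome 0.01 (1439 windows), against -0.11 on autosomes.

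**Figure D2:**
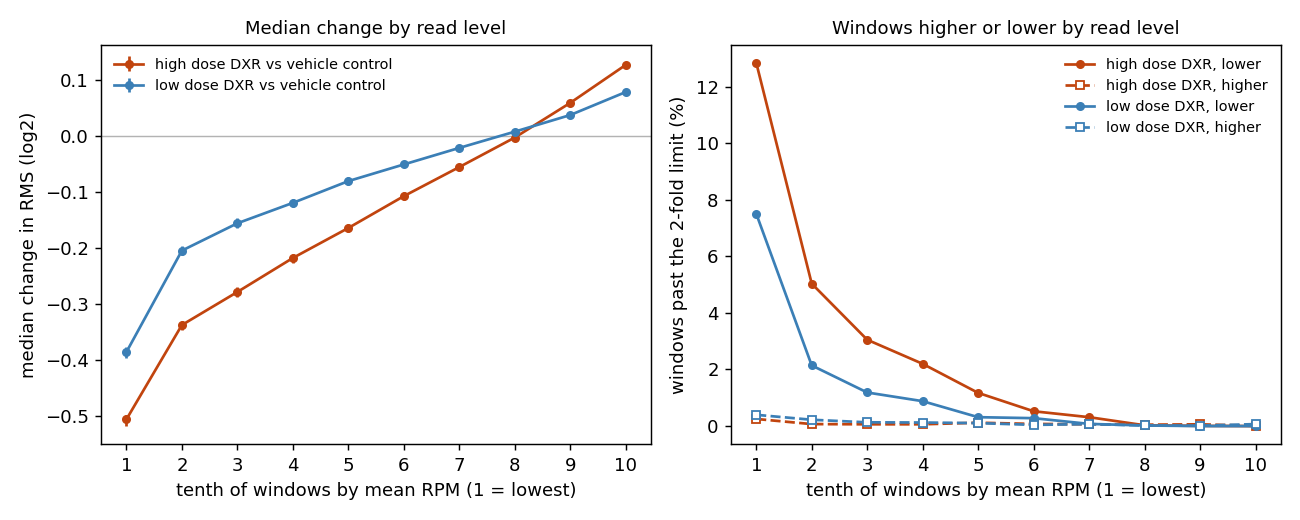
Median change in RMS (left, log2) and share of windows past the 2-fold limit (right, percent) for each decile of windows by mean RPM, in the high and low dose libraries against the control. Error bars are 95% order-statistic intervals of the median; the high dose median runs from -0.51 in the lowest decile to 0.13 in the highest, and 12.8% of windows in the lowest decile were lower.

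The second comparison asked the same question for the low dose. Under the naming rule, the largest upward change was in an intron of Pygl, which encodes liver glycogen phosphorylase (ENSMUSG00000021069; chromosome 12, 70192501 to 70193000), where RMS was 0.415 in the control library, 2.47 at the low dose and 1.82 at the high dose. A copy of 5.8S ribosomal RNA sequence on chromosome 18 (n-R5-8s1, 73533001 to 73533500) had RMS 0.832, 3.54 and 2.08 in this order. An exon 7 window of Plk1, a mitotic kinase gene, had RMS 0.538 in the control library and 2.29 at the low dose. The largest downward change under the rule was at exon 13 of Iars2, a mitochondrial tRNA synthetase gene (chromosome 1, 185312001 to 185312500), with RMS 2.55 in the control library, 0.144 at the low dose and 0.314 at the high dose. In an intron of Grip1 (chromosome 10, 119944001 to 119944500), RMS was 1.74 in the control library and both treated libraries were listed at 0.

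The other upward genes at the low dose were Lrrc3, Cacna1i, Tnfrsf11a, Fermt2, Myh7b and Syt17, with changes from 1.24 to 1.36. Among them, Tnfrsf11a encodes the receptor RANK, and its intronic window had RMS 0.396 in the control library and 2.04 at the low dose. The other downward genes were Lrrc16a, AC126552.1, Dock4, Hcls1, Mrc2, Ltbp1, Hydin and Cacnb2. Hydin, a gene of the ciliary axoneme, had an intronic window with RMS 1.70, 0.0562 and 0.110 in the control, low dose and high dose libraries. Cacnb2, a calcium channel subunit gene, had one with RMS 1.81 in the control library that was listed at 0 at the high dose. AC126552.1 was the 1 gene named at both doses, with RMS 4.58 in the control library, 0.825 at the low dose and 0.690 at the high dose. All 20 changes under the naming rule had the same sign at the high dose, which the shared control library also favours. With the pseudocount multiplied by 3, 0 of the 10 upward and 2 of the 10 downward windows stayed past the limit. Over all windows, 172 were higher and 1777 lower at the low dose, with a median change of -0.05 (95% interval -0.06 to -0.05). Quantile normalization gave 729 higher and 873 lower windows, and subtraction of the trend 981 and 295. The median was above 0 after quantile normalization, after division by library medians and when RPM replaced RMS, and the pseudocount divided or multiplied by 3 gave 6981 or 5 lower windows.

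The third comparison set the high dose against the low dose. Windows past the limit between the doses, chosen after their values were seen, included an exonic window of Rpa1, which encodes a subunit of the single-stranded DNA binding complex of replication (chromosome 11, 75301001 to 75301500). It was listed at 0 at the high dose, with RMS 1.70 at the low dose. An exon 4 window of Zdhhc23, a palmitoyltransferase gene, had RMS 2.81 at the low dose and 0.533 at the high dose. Higher at the high dose were an intronic window of the zinc transporter gene Slc39a11, with RMS 0.429 and 1.93 at the low and high dose, and one of Jakmip1 with 0.955 and 2.98. Over all windows, 42 were higher and 472 lower at the high dose, and the median change was -0.04 (95% interval -0.04 to -0.04). The SD of the change over windows was 0.29, against 0.39 for high dose with control and 0.36 for low dose with control. With the trend subtracted, 143 windows were higher and 197 lower, quantile normalization gave 43 and 131, and division by library medians or quantile normalization brought the median above 0.

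Regions that moved at both doses were also compared. Windows higher at both doses numbered 23, with 17 of them in 19 genes, and those lower at both numbered 785, with 511 of them in 494 genes. The higher ones included exon 3 of Myom3, a sarcomere gene (RMS 0.498, 1.93 and 1.89 in the control, low dose and high dose libraries), exonic sequence of the integrin gene Itgb4 (1.39, 3.58 and 4.10) and exon 5 of the chaperone gene Dnajc18 (0.866, 2.54 and 2.92), chosen after their values were seen. No window passed the limit in opposite directions at the 2 doses. Shuffling the 3 values within windows gave a mean of 66.05 windows higher at both doses, more than observed, and 270.8 lower, fewer than observed. Independent lists would share 0.142 and 44.7. The 2 changes correlated across windows, which are not independent replicates, at r = 0.70 (0.50 after shuffling). Their covariance was 0.0993 against 0.0663 after shuffling. Shuffling treats the 3 libraries as alike. A control library unlike both treated ones can thus raise the correlation, covariance and lower overlap without any effect of DXR. The variance of trend-corrected values specific to 1 library was 0.0771 for the control, 0.0358 for the low dose and 0.0445 for the high dose. Quantile normalization and subtraction of the trend each left fewer windows changed at both doses, as given below. RMS was highest in the control and lowest in the high dose library, with the low dose between, in 27.9% of windows, and the opposite order held in 14.99%. The low dose library was not between the others in most windows, being highest in 28.4% and lowest in 28.8%. Among 3 alike libraries, any 1 would also lie outside the others in most windows, so this does not speak against an order by dose.

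Imprinted loci were the first gene lists examined. All 5 paternally methylated loci, which carry methylation in sperm, had windows annotated to the gene, and 0 of these 22 windows passed the limit at either dose. These windows were taken by gene annotation and not chosen to cover the imprinting control regions. A first-exon window of H19 (chromosome 7, 142576501 to 142577000) had RMS 5.58 in the control library, 5.94 at the low dose and 5.65 at the high dose. One of Meg3 (chromosome 12, 109546001 to 109546500) had 3.01, 2.85 and 3.05. Upstream of H19, where its imprinting control region lies, all 5 listed windows (chromosome 7, between 142579501 and 142582500) were below control at the high dose. Their changes, from -0.74 to -0.16, were short of the limit and not corrected for the trend in RPM and factor. Over all windows, 60.8% were below control at this dose. The strongest of the 5 (142580001 to 142580500) had RMS 4.20, 4.60 and 3.69. That with the largest change (142581001 to 142581500) had 1.60, 1.04 and 0.651. Both were chosen after their values were seen. Within Rasgrf1, exon 2 had RMS 0.959, 2.07 and 2.57, and exon 9 had 2.56, 2.51 and 1.13, in the same order. Windows of the maternally methylated loci were also taken by gene annotation. They included sequence with signal in the control library, such as an Igf2r window with RMS 5.34, and do not stand for the regions unmethylated in sperm. Of these loci, 9 of 19 were measured, with 44 windows, and 4 genes had a window lower at the high dose. These were Grb10 (exonic, RMS 3.48, 1.07 and 0.769), Gnas (exonic, a change of -1.06), Slc38a4 and Airn, a noncoding RNA gene within the Igf2r locus. At the low dose only the Grb10 window passed. A first-exon window of Gnas (chromosome 2, 174345001 to 174345500) had RMS 4.16, 2.84 and 1.89, while 2 such windows of Peg10 had RMS 0.952 and 1.65 in the control library and 0.973 and 1.61 at the high dose. The Gnas window lies near the far end of the gene (174284320 to 174346744, plus strand), so it need not be a promoter window. The first-exon window of Grb10 (chromosome 11, 12027501 to 12028000) had RMS 1.11, 1.12 and 0.814. The median of the maternally methylated list was -0.31 at the low dose, at percentile 0.605 of random lists, and -0.22 at the high dose, at percentile 25.8. After quantile normalization the low dose median was -0.21, at percentile 1.34. It was 0.06 (percentile 73.7) after the trend in RPM and factor was subtracted, and with the window of largest RMS per gene it lay at percentile 19.2. With that window the high dose median was 0.0975. The paternally methylated list lay at percentile 85.5 at the low dose (median 0.04) and 63.7 at the high dose (median -0.06, but 0.04 after quantile normalization).

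Genes of the germline were examined next. Spermatogonial genes had 13 of 20 members measured, and 5 of them had a lower window at the high dose: Foxo1, Kit, Ret, Zbtb16 and Gfra1. Lower were 6 of the 150 windows of this list, against 2.85% of all gene-annotated windows. Some of these genes had many windows, with 34 in Kit, 29 in Zbtb16 and 18 in Gfra1. Intronic windows of Gfra1, the GDNF co-receptor of spermatogonial stem cells, went from RMS 2.32 and 2.37 in the control library to 0.580 and 0.657 at the high dose. In Sall4 a window went the other way, from 0.428 to 1.48, short of the limit, although the mean change over its 13 windows was -0.01. Of the spermatid and sperm genes, 21 of 30 were measured, and Izumo1 and Acr had a lower window at the high dose. Izumo1 encodes the sperm protein that binds the egg, and its exonic window had RMS 2.71 in the control library, 1.97 at the low dose and 0.724 at the high dose. Acr, the acrosin gene, had 2.49, 0.923 and 0.673 in exon 2. Germline-specific genes, which are methylated at their promoters in somatic cells, had 11 of 24 members measured, none with a first-exon or upstream window in the table, and 0 windows passed the limit at the high dose. Exonic sequence of Mov10l1 was lower at the low dose (1.20 to 0.177). The medians at the high dose were -0.19 for spermatogonial genes (percentile 42.9; 0.006 after quantile normalization), -0.09 for spermatid and sperm genes (67.5) and -0.20 for germline-specific genes (15.9). At the low dose they were -0.16 (16.4), 0.01 (92.3) and -0.05 (62.8). Without first-exon and upstream windows, the spermatid and sperm genes had a low dose median of 0.05 (98.96), above the range of random lists. Their high dose median was then -0.09 (84.63).

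Markers of other cell types stood within the range of random lists. Sertoli and Leydig cell genes, 9 of 20 measured, had a median of -0.33 at the high dose (percentile 6.68) and -0.16 at the low dose (23.8), with 0 windows past the limit. Among them, intronic windows of Lhcgr and Wt1 had changes of -0.92 and -0.85 at the high dose. Leukocyte and epididymal epithelium genes, 9 of 17 measured, had medians of -0.26 (22.7; 0.007 with the trend subtracted) and -0.13 (35.5). An intronic window of Sfpi1, the myeloid transcription factor gene PU.1, was lower at both doses, with RMS 2.31, 0.305 and 0.309. Exon 16 of Cdh1, the E-cadherin gene, was higher at the low dose, with RMS 1.65, 4.11 and 3.72.

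Among genes of the drug response, DNA damage response genes (22 of 30 measured) had lower windows at the high dose in Mre11a and Prkdc, which act in double-strand break repair. The exon 19 window of Mre11a had RMS 2.37, 1.17 and 0.455 in the control, low dose and high dose libraries. A window of the checkpoint kinase gene Atm (chromosome 9, 53442501 to 53443000) was higher at the low dose alone, with RMS 0.607, 2.23 and 0.561. It overlaps exon 1 of an annotated transcript and also an exon of another number, so it need not lie at the main promoter. The list medians were -0.16 at the high dose (percentile 43.3) and -0.05 at the low dose (72.0). For anthracycline transport and metabolism (14 of 17) they were -0.17 (36.8; 0.04 after quantile normalization) and -0.12 (26.4; 0.01 with the trend subtracted). Por, the cytochrome P450 reductase gene, had 2 lower windows at the high dose, with RMS 2.98 and 2.28 in the control library and 0.990 and 0.680 at the high dose. Its exon 1 window went from 0.699 to 1.63, and the mean change over its 16 windows was 0.07. Oxidative stress defence (16 of 24) gave -0.17 (62.2; 0.04 with the trend subtracted) and -0.14 (27.9), with lower windows in the glutathione peroxidase genes Gpx3 and Gpx4 at the high dose alone. With the window of largest RMS per gene its medians were 0.16 (98.85) and 0.06 (83.8). Without first-exon and upstream windows they were -0.02 (98.47), above the range of random lists, and -0.12 (44.65). Apoptosis genes (11 of 20) gave -0.07 (86.9) and -0.04 (72.3), both above 0 after quantile normalization (0.04 and 0.06), with lower windows in Bid and Casp9 at the high dose and in Tnfrsf10b at the low dose. With the window of largest RMS per gene, the low dose median of apoptosis genes was -0.27, at percentile 0.71.

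DNA methylation and chromatin genes (23 of 30) gave medians of -0.22 at the high dose (percentile 13.5) and -0.12 at the low dose (23.8). An exonic window of Dnmt1, the maintenance methyltransferase gene (chromosome 9, 20912501 to 20913000), had RMS 1.90 in the control library, 0.144 at the low dose and 0.651 at the high dose, and was lower at the low dose. Windows of Hdac1 and Kdm5b were lower at the high dose, and Tet2 exon 6 had a change of 0.60 there, although the mean over the 9 windows of Tet2 was -0.29. Only 7 of 39 Hox genes had a window in the table, with medians of 0.05 (96.9) and 0.06 (93.6). Other developmental regulators (11 of 36) gave -0.07 (86.6; 0.08 after quantile normalization) and 0.04 (95.7). Exon 13 of the eye development gene Pax6 was lower at both doses, with RMS 2.81, 0.908 and 0.755. Housekeeping genes (6 of 18) gave -0.26 (12.2) and -0.10 (43.1; 0.02 with the trend subtracted). All 4 windows of this list that overlap exon 1 of an annotated transcript, adjacent pairs in Gapdh and Polr2a, were lower at the high dose. Each also overlaps an exon of another number, so they need not lie at the main promoters. For Gapdh (chromosome 6, 125163001 to 125163500) RMS was 3.58, 1.95 and 1.36. Another exonic window of Polr2a (chromosome 11, 69735501 to 69736000) went from RMS 2.51 to 4.62 at the high dose. The mean change over the 5 windows of Polr2a was -0.18. Olfactory and vomeronasal receptor genes, 75 in number, lay above the range of random lists at both doses, with medians of -0.02 at the high dose (percentile 99.96) and -0.003 at the low dose (98.7), although they were 0.08 and 0.04 after quantile normalization (percentiles 99.1 and 89.4). The receptor list lay within the random range with the trend subtracted (94.4 and 89.0) and with the window of largest RMS per gene (86.4 and 36.2). Over the 15 lists other than receptors, 30 of 1033 windows (2.90%) were lower and 0 higher at the high dose, against 2.85% lower among all gene-annotated windows.

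**Figure D3:**
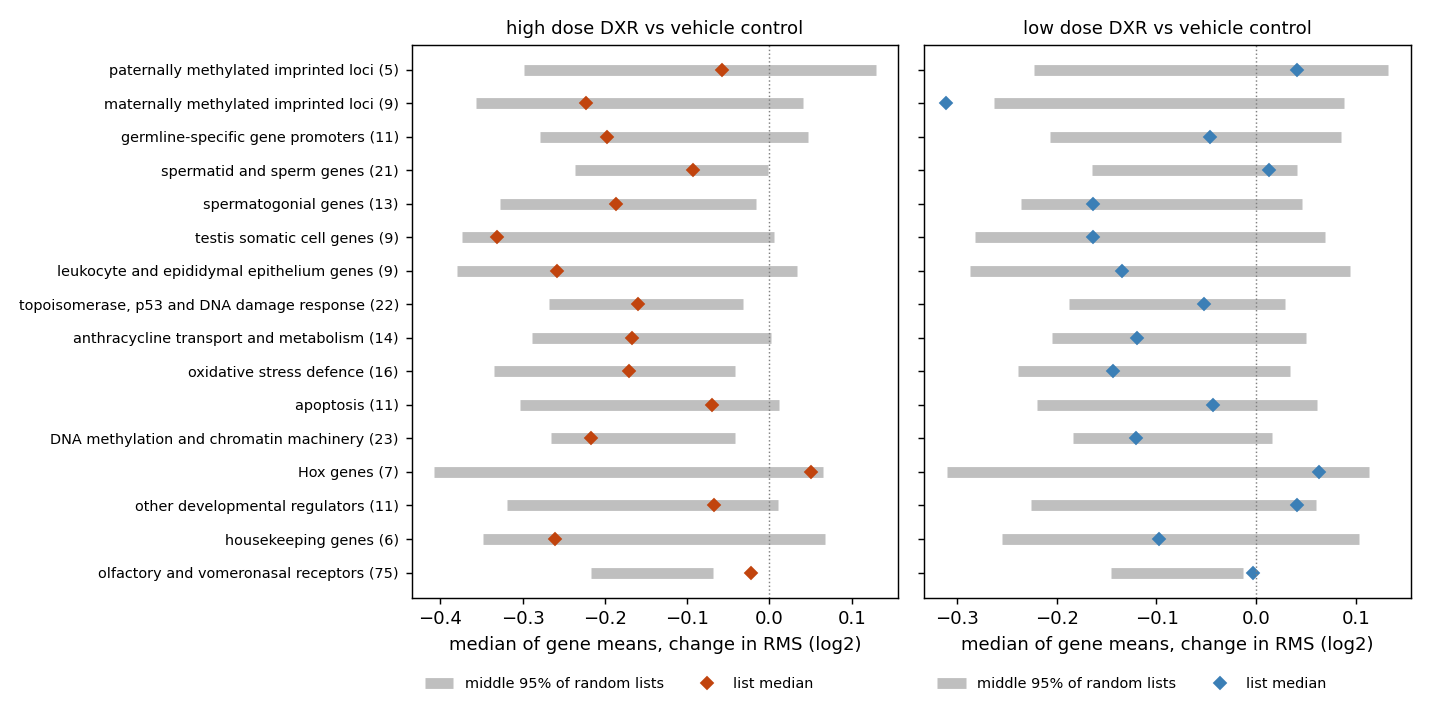
Median change in RMS (horizontal axis, log2, each gene the mean of its windows) for 16 gene lists at the high dose (left) and the low dose (right), with the number of genes measured in brackets. Grey bars span the middle 95% of 10000 random lists of matched mean RMS; the maternally methylated list at the low dose (-0.31, but 0.06 with the trend subtracted) and the receptor list at the high dose (-0.02, but 0.08 after quantile normalization) and the low dose (-0.003, but 0.04 after it) lie outside them.

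Ribosomal DNA sequence was covered by 12 windows around Rn18s-rs5, a gene related to 18S ribosomal RNA (chromosome 17, 39846354 to 39848202 in GRCm38.p6; windows from 39843001 to 39849000). In the 6 windows before the gene, RPM summed to 63.8 in the control library, 192.4 at the low dose and 92.4 at the high dose. In the 5 windows over the gene the sums were 279.0, 459.6 and 418.6. The median change of the 12 windows was 0.81 at the low dose and 0.33 at the high dose. Reads of this kind can be shared between the many copies of ribosomal DNA, and which copy they came from is unknown.

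**Figure D4:**
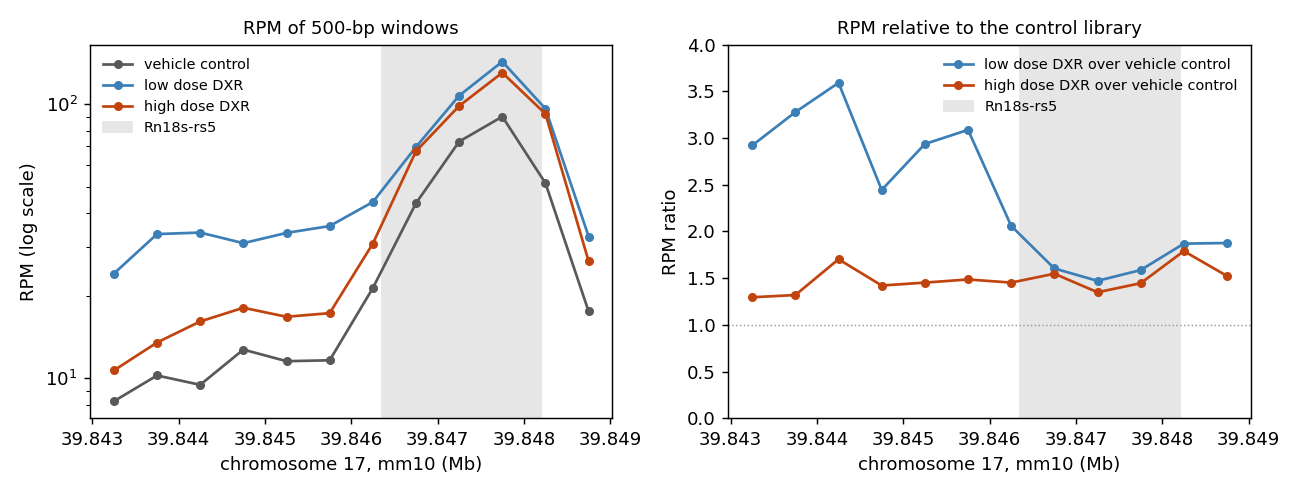
RPM of each 500-bp window (left, log scale) in the 3 libraries and RPM relative to the control library (right) along chromosome 17 around Rn18s-rs5 (grey band). Before the gene the low dose ratio runs from 2.44 to 3.59 and the high dose ratio from 1.30 to 1.70; over the gene they run from 1.47 to 2.06 and from 1.35 to 1.79.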

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

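The tests of depth, of the share of X-bearing sperm, of methylation loss and of somatic cell DNA, and the test of enrichment on the RPM deciles, were chosen after the results were seen. That of enrichment on ribosomal DNA and that of X and Y copy number were not, although the latter had been set for doubled RPM alone.

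Changes between libraries were computed on RMS. RPM summed over the 12 windows of Rn18s-rs5 was higher in both treated libraries than in the control library, 1.90 times at the low dose and 1.49 times at the high dose. Of 162 other windows with a factor from 7 to 13 and like RPM, the median low dose change was 0.12. It was 0.81 for the 12 windows, a difference of 0.69. An upper percentile of the 162 changes was 0.92, and 5 of the 12 windows lay above it. At the high dose, the medians were 0.33 for the 12 windows and 0.24 for the others. There 1 of the 12 lay above the same percentile (0.59). The low dose difference speaks against enrichment that follows read level and CpG content as the whole cause at that dose. It does not exclude it, since the spreads overlap and the 12 windows are adjacent to each other. Somatic cell DNA, whose ribosomal DNA may be more methylated, stays open. The only 4 first-exon or upstream windows, in Gnas, Peg10 and Grb10, already carried signal in the control library, with RMS from 0.952 to 4.16. Their median low dose change (0.0723) can therefore not show whether somatic DNA was present. A change in ribosomal DNA methylation or copy number with DXR was not tested and cannot be separated from a difference between single libraries.

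More windows were lower than higher in the treated libraries. If an RPM step stands for the same number of reads in each library, relative depths of 1.09 (low dose) and 0.993 (high dose) argue against a difference in sequencing depth. A difference in enrichment between libraries is a candidate explanation, since the median high dose change was 0.13 in the highest RPM decile and, with RMS above 1 in all 3 libraries, 0.14 in the highest and -0.09 in the lowest; over all windows the lowest decile depends on the filter. Loss of methylation at weakly enriched windows under DXR cannot be told apart from the state of the control library. The variance of trend-corrected values specific to 1 library was 1.73 times as large in the control library (0.0771) as in the high dose library (0.0445), and no other control library was there to compare.

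X and Y windows had higher changes at the high dose than autosomal windows of like RPM and factor, by 0.10 on X and 0.09 on Y. A changed share of X-bearing sperm would move X and Y in opposite directions, and Y (0.0923) went the same way as X. Each sperm carries either X or Y, so their windows may have been matched with autosomal windows of lower methylation. With X and Y RPM and RMS doubled, in the matching and in the change, the high dose differences were -0.02 on X and -0.0259 on Y. Both lay within 0.03 of 0, a bound set beforehand for doubled RPM alone. The interval on Y was -0.0473 to -0.0025, and its median lay below that of the lowest autosome (-0.0165). At the low dose the Y value after doubling was -0.0545, beyond 0.03 in size, and no other biological explanation was tested.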

How the results depend on the processing

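RPM in place of RMS, windows with RMS above 1 in all 3 libraries, and subtraction of the trend were chosen after the data were seen; the other settings were not. No paired analysis was possible because each group had 1 library. All 10 upward and 10 downward changes under the naming rule at each dose kept their direction under the 6 settings tried on them. A pseudocount cannot change the direction, and the windows were chosen for large changes, so this was largely given beforehand. Of the values, 192 stayed within 1.5 times the reported one and 48 did not. Of the counts of windows, 21 stayed within 1.5 times the reported value and 87 did not; of the gene list medians, 73 stayed within the order-statistic interval of the reported median and 17 left it. A further 6, of lists beyond the range of random lists, changed sign, some within that interval and some beyond it. Of all 96 list medians under the alternatives, 35 had the opposite sign to the reported one. Values below are windows higher and lower, then the median change, for high dose with control, low dose with control and high with low dose, then windows changed at both doses. For the limits and the pseudocount, the construction itself moves the counts; for the others, the cause was not tested. Read depth per window is unknown, so its part in these shifts could not be measured.

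With the pseudocount multiplied by 3, counts were 2 and 15 (-0.0646), 1 and 5 (-0.0347), and 0 and 2 (-0.0257), with 2 at both doses. Divided by 3, they were 770 and 12168 (-0.13), 1118 and 6981 (-0.0672), and 660 and 3544 (-0.0526), with 4401 at both. A limit of 1.5-fold gave 2667 and 19436, 3217 and 12504, and 1612 and 6333, with 8946 at both; a limit of 4-fold gave 0 and 2, 0 and 1, and 0 and 0, with 0 at both.

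Division by library medians gave 335 and 2213 at the high dose and 81 higher for high with low dose, with 499 at both; the medians changed sign to 0.0348, 0.0224 and 0.0207. Quantile normalization gave 694 and 993, 729 and 873, and 131 lower for high with low dose, with 422 at both; the medians changed sign to 0.0107, 0.0054 and 0.0073. It also changed the sign of the olfactory and vomeronasal receptor medians, to 0.0793 at the high and 0.0374 at the low dose. Subtraction of the trend gave 989 and 424, 981 and 295, and 143 and 197, with 324 at both, and by construction medians near 0. It changed the sign of the receptor medians (0.0572 high, 0.0438 low) and of the maternally methylated median at the low dose (0.0629). With the window of largest value per gene, the receptor median at the high dose was 0.0142.

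Windows at or above the median mean gave 57 and 493, 50 and 189, and 6 and 87, with 64 at both; the medians changed sign at the high (0.0064) and low dose (0.0103) and were -0.0033 for high with low dose. Windows with RMS above 1 in all 3 libraries gave 41 and 263 (-0.0129), 34 and 126 (-0.00080), and 1 and 41 (-0.0090), with 35 at both. Each gene counted once gave 8 and 177 (-0.15), 5 and 74 (-0.0842), and 1 and 19 (-0.0628), with 39 at both. Autosomes alone gave medians of -0.11, -0.0577 and -0.0435. RPM in place of RMS gave medians of -0.0939, 0.0080 (changed sign) and -0.0890, with 16 higher for high with low dose.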

Other observations

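The genes named here were chosen after their values were seen; the test of gene-wide shifts was fixed before its result was seen. In some genes most windows lay above, or most lay below, the trend in RPM and factor at the high dose. Chl1, the adhesion molecule gene with a named window, had 6 of 6 windows above the trend at the high dose, with a mean of 0.43. Manba, a lysosomal mannosidase gene, had 8 of 9 below (-0.52), Dgki, a diacylglycerol kinase gene, 8 of 10 below (-0.46), and Lrp6, a Wnt co-receptor gene, 6 of 7 below (-0.44). Without the 1 window furthest from the trend, the means were 0.19 for Chl1, -0.44 for Manba, -0.35 for Dgki and -0.34 for Lrp6.

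A change shared along a gene may underlie these genes. Over 3902 genes with 5 or more windows at least 1 kb apart, the SD of gene means at the high dose was 0.14, which is 1.09 times the mean after shuffling changes among windows (0.13). The bounds set beforehand left a ratio of this size undecided, and at the low dose the ratio was 1.03. Across windows, which are not independent, changes of neighbours 500 bp apart correlated at r = 0.34 and of those 1 kb apart at r = 0.04 at the high dose.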
